A study of Mus musculus with 29 samples.

How the data were processed

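Each of 29 arrays (Mouse Gene 2.0 ST, from Affymetrix) measured RNA from the spleen cells of a single mouse. Per the labels, the animals were young adult female F1 hybrids of B6 and CBA mice. They were of 3 genotypes: R6/1, zQ175 and mice without a Huntington's disease allele (WT). Unimmunized mice gave 5 arrays per genotype. Immunized mice gave 5 arrays each for R6/1 and zQ175 and 4 for WT. Immunization used 3 peptides coded by exon 1 of the human huntingtin gene (amino acids 1 to 17, 49 to 60 and 74 to 88) that were coupled to the carrier protein keyhole limpet haemocyanin and given with alum. R6/1 mice received the first dose at 6 to 12 weeks and zQ175 mice at 15 to 24 weeks. The age of WT mice at that dose and the ages of unimmunized mice are not given in the sources used here. Each immunized mouse was boosted 2 times, and its spleen was taken 10 days after the last boost. No group received carrier and alum without the peptides. Spleens were broken up mechanically and red cells were lysed with ammonium chloride before RNA was purified.

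The deposited values are log2 expression of each probe set, already scaled between arrays by the authors by a method that is not given in the sources used here. Array medians lay between 6.206 and 6.331, lower quartiles between 4.924 and 5.095 and upper quartiles between 8.003 and 8.216, so no further normalization was applied. Pairwise correlations between arrays ran from 0.9578 to 0.9927, and no 2 arrays were identical. All 29 arrays had high Xist (11.9 to 12.7) and low Kdm5d (3.64 to 4.65), Eif2s3y (4.25 to 4.98) and Uty (3.78 to 5.22), as female mice have. Of 41345 probe sets, 190 were controls, 23521 carried 1 gene symbol, 1814 carried several and 15820 carried none. The probe set with the highest mean stood for each of the 22180 genes with a symbol of their own. A gene was tested when its value was above the median of the whole table (6.267) in at least 4 arrays, which left 13410 genes. A gene reference of assembly GRCm38.p6 was used to check symbols by gene identifier, which changed 0 of them and held no entry for 193 identifiers, and to find the neighbours of Htt. The deposited files name no genome build.

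A linear model with 1 mean for each of the 6 groups was fitted to each gene with limma 3.58.1 in R 4.3.3, with 23 residual degrees of freedom and moderated standard errors. The 10 contrasts were the immunization response in each genotype, each Huntington's disease genotype against WT among unimmunized and among immunized mice, and the 3 differences between immunization responses. Adjusted p-values are Benjamini-Hochberg values over the genes tested. A gene is said to have risen or fallen, or to have passed, when its adjusted p is under 0.05. Unless another test is named, every p in the text is from a two-sided limma test. Counts at an unadjusted p under 0.05 can be set against the 670 genes that chance would give.

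Gene lists of cell types, immune and stress responses, cell cycle phases and metabolic pathways, 35 in all, were compared with the other genes by the limma function camera with a preset correlation of 0.01 between genes. One of them had under 5 tested genes, which left 34, and their adjusted p is over those 34. No list call held in any comparison when camera estimated the correlation from the data, so that p is given beside each list. The function fry, preranked enrichment with fgsea 1.28.0 and an exact permutation test of the list mean per array were run as alternatives, the last of these chosen after the list results were seen. The study's notes mention gene set enrichment without its settings. The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from what is said in the text to have been chosen later.

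By that rule, the genes named were the 8 largest rises and the 8 largest falls among genes that passed in each main comparison, or the 3 with the smallest p in a direction in which fewer than 3 passed, and up to 4 members of each list called. In the other comparisons the numbers were 5 of each direction and 2 of each list. Predicted genes, olfactory and vomeronasal receptors, small RNA genes and variable segments of antigen receptors were only counted. Htt is given in every group. Not every gene that the rule takes is named. Genes picked in this way tend to lie beyond the other group's mean in most arrays, so such counts of arrays are no added support. The 4 immunoglobulin segments that passed in WT mice were named outside the rule, after their values were seen.

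The same code was tested on simulated data in which 200 genes were changed by 1.5-fold or 2-fold. In the zQ175 immunization response it recovered 86.9% of genes changed 1.5-fold and 97.3% of those changed 2-fold. The shares were 85.5% and 97.4% for R6/1 and 84.9% and 97.1% for WT. For the difference between the zQ175 and WT responses they were 61.5% and 91.7%. The simulated noise was independent between genes and arrays.

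Alternatives were quantile normalization, centring of each array, no filter and a stricter filter (above the 65th percentile of the table), the mean of all probe sets of a gene, robust moderation with a trend, array weights, only the arrays of the groups compared, the number in the array's name as a block, the erythroid and neutrophil list means as covariates, and leaving out each array in turn. Chosen after the data were seen were the immediate early list mean as a covariate and leaving out R6/1 immunized array 4, which had the lowest correlation with the others, together with zQ175 unimmunized array 1, which differed from the rest of its group in list means, the immediate early one among them. Probe sets without a symbol were tested apart from the genes. Raw array images and protein or antibody measurements were not used here.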

Results

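The data were spleen transcriptomes of 29 female mice, 1 array per mouse. They asked how R6/1 mice, which carry a human huntingtin exon 1 transgene, zQ175 mice, which carry an expanded huntingtin exon 1 knocked into the mouse Htt gene, and WT mice respond in the spleen to immunization with 3 huntingtin exon 1 peptides. Unimmunized mice gave 5 arrays per genotype, and immunized mice gave 5 (R6/1), 5 (zQ175) and 4 (WT). Expression of 13410 genes was tested. The values below are log2 differences with their standard error (SE) unless stated otherwise.

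The first comparison asked how zQ175 spleens differed after immunization from those of unimmunized zQ175 mice. Immediate early genes, heat shock genes, inflammatory genes and neutrophil granule genes were higher after immunization, and 9 of 18 red pulp macrophage genes and 7 of 17 natural killer (NK) cell genes were lower. With an estimated correlation no list passed, red pulp macrophages having an adjusted p = 0.453 with an estimated correlation and NK cells one of 0.676. The inducible heat shock protein 70 genes Hspa1b and Hspa1a rose most, by 4.43 ± 0.72 and 3.71 ± 0.51 (21.5-fold and 13.1-fold, n = 5 against 5, adjusted p = 0.000141 and 4.16e-05). Of the genes tested, 1881 passed, 886 of them higher and 995 lower (855 and 1712 under quantile normalization). With the erythroid and neutrophil list means as covariates, 461 were higher and 302 lower, which turns the larger share. Changes of at least 2-fold were mostly rises, with 120 genes higher and 5 lower. Each gene named for this comparison lay beyond the unimmunized mean in 5 of 5 immunized arrays.

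Of 25 immediate early genes, which cells induce within minutes to hours of stimulation, 24 rose and 0 fell, both over all genes and adjusted over the list alone. Their mean change was 1.03, with an adjusted p = 0.092 with an estimated correlation. Among them were the stress transcription factor gene Atf3 (2.23 ± 0.29, adjusted p = 2.77e-05), the nuclear receptor gene Nr4a3 (1.70 ± 0.23), the AP-1 gene Fosl2 (1.54 ± 0.22) and the early lymphocyte activation marker Cd69 (1.22 ± 0.17). Klf4, a zinc finger transcription factor gene, rose by 2.14 ± 0.39, and Rgs16, a regulator of G protein signalling, by 2.10 ± 0.27. Of 12 heat shock genes 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a mean change of 1.08 and an adjusted p = 0.0634 with an estimated correlation. The chaperone genes Hsph1 and Dnajb1 rose by 0.99 ± 0.16 and 0.93 ± 0.12. Of 27 genes of the TNF and NF-kB response 15 rose and 1 fell (17 and 2 adjusted over the list alone), with a mean of 0.54 and an adjusted p = 0.092 with an estimated correlation. They included the monocyte chemokine gene Ccl2 (1.37 ± 0.17), Ier3 (1.32 ± 0.16), the NF-kB inhibitor gene Tnfaip3 (1.56 ± 0.23) and the NF-kB subunit gene Rel (0.76 ± 0.11). The unfolded protein response list had 6 of 22 genes that rose and 0 that fell (7 and 0 adjusted over the list alone), with an adjusted p = 0.453 with an estimated correlation. Ddit3, a stress transcription factor gene, rose by 0.99 ± 0.22 and the chaperone gene Dnajb9 by 1.02 ± 0.20.

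The immediate early list moved with a shift among the unimmunized zQ175 arrays. The mean of the immediate early list was 11.69 ± 0.031 (SD, n = 5) in immunized zQ175 spleens and 10.66 ± 0.58 (SD, n = 5) in unimmunized ones, while the means of the other 4 groups lay between 11.38 and 11.56. Among the unimmunized zQ175 arrays, array 1 had a mean of 11.63 and the remaining 4 lay between 10.22 and 10.74. The heat shock list had a mean of 9.90 ± 0.087 (SD, n = 5) in immunized and 8.83 ± 0.44 (SD, n = 5) in unimmunized zQ175 spleens, against 9.19 to 9.43 in the other groups. Against WT mice it stood at -0.40 ± 0.15 among unimmunized and 0.68 ± 0.16 among immunized zQ175 mice, and the TNF and NF-kB list at -0.23 ± 0.089 and 0.37 ± 0.094. Fitted with the immediate early list mean as a covariate, a choice made after the data were seen, the comparison gave 0 genes by limma against 1881 without it, and the median SE went from 0.0923 to 0.143. A lost call did not always mean a lost change. Atf3 went from 2.23 to 0.418 ± 0.129 in that fit, but Camp from 2.2 to 3.12 ± 0.686. Atf3 belongs to the list whose mean is the covariate. For the genes of that list the loss was built into the fit and says little about their change.

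**Figure D1:**
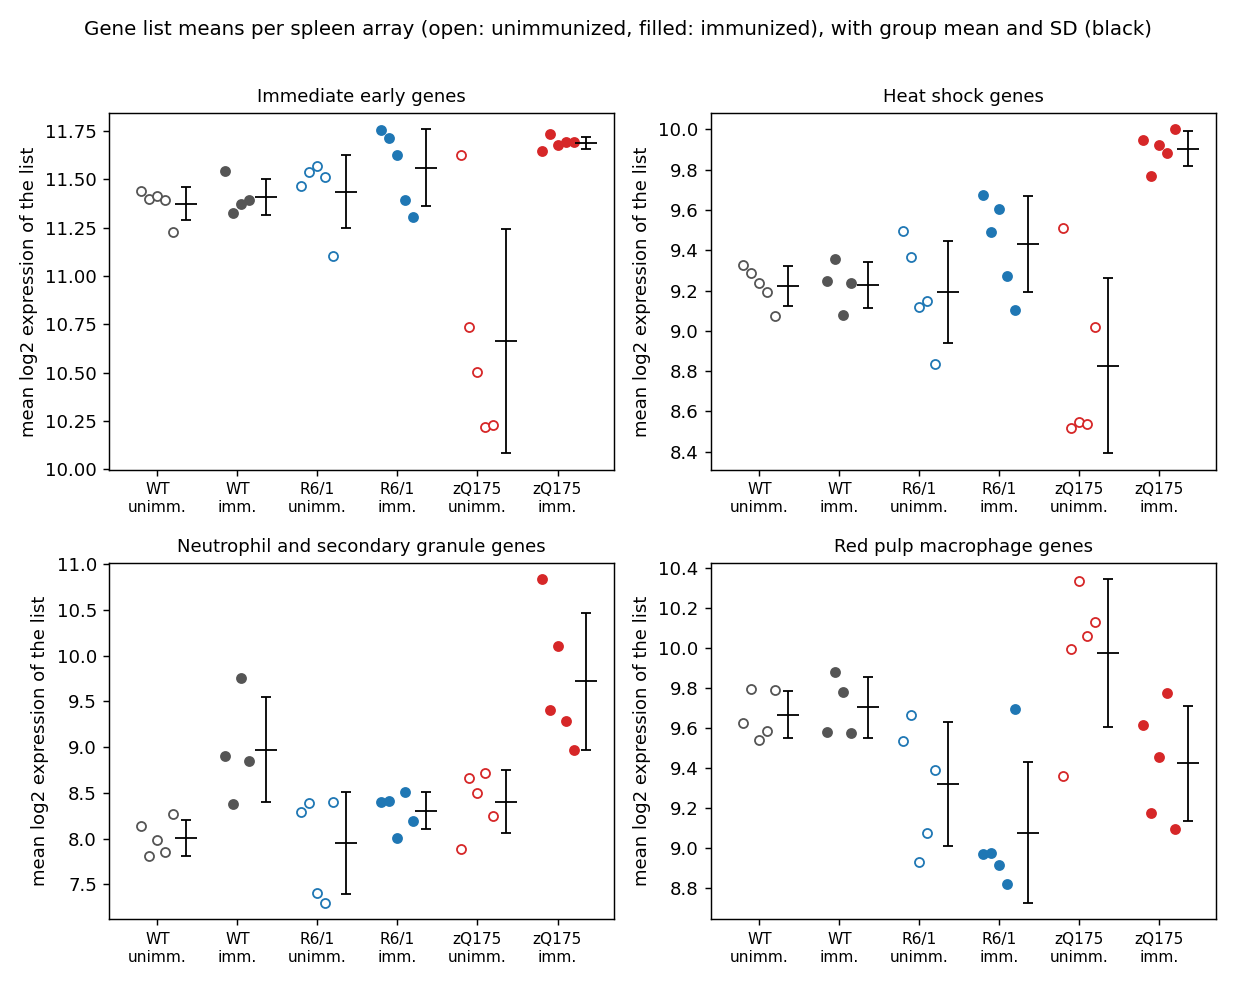
Each point is 1 spleen array and gives the mean log2 expression of a gene list (vertical axis) by group (horizontal axis). Open points are unimmunized and filled points immunized mice, and black marks give the group mean and SD. The unimmunized zQ175 arrays 2 to 5 had immediate early means of 10.22 to 10.74, below the lowest array of the other groups (11.10).

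Neutrophil genes were also higher in immunized zQ175 spleens. Of 21 neutrophil and secondary granule genes 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a mean change of 1.31 and an adjusted p = 0.172 with an estimated correlation. Chil3, which encodes a chitinase-like protein of myeloid cells, rose by 2.29 ± 0.44, the cathelicidin gene Camp by 2.20 ± 0.45, Olfm4 by 2.05 ± 0.33, Cd177 by 1.81 ± 0.33 and Lcn2 by 1.63 ± 0.29. Of 10 primary granule genes, which are transcribed in granulocyte precursors, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a mean of 0.92 and an adjusted p = 0.172 with an estimated correlation. The elastase gene Elane rose by 1.74 ± 0.36, the myeloperoxidase gene Mpo by 1.52 ± 0.29, the proteinase 3 gene Prtn3 by 1.42 ± 0.27 and the granulocyte transcription factor gene Cebpe by 1.24 ± 0.25. Of 11 basophil, mast cell and eosinophil genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.453 with an estimated correlation), among them the histidine decarboxylase gene Hdc (1.21 ± 0.20) and the basophil protease gene Mcpt8 (1.01 ± 0.25). Of 13 megakaryocyte and platelet genes 4 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.430 with an estimated correlation), among them Ppbp (0.63 ± 0.18), whose adjusted p was 0.0592 without zQ175 immunized array 3.

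Red pulp macrophage genes fell in 9 of 18 cases and rose in 0 (16 and 0 adjusted over the list alone), with a mean change of -0.55 and an adjusted p = 0.453 with an estimated correlation. Marco, a scavenger receptor gene, fell by 0.76 ± 0.13, the apoptotic cell receptor gene Mertk by 0.76 ± 0.20, the complement gene C1qa by 0.59 ± 0.16 and Adgre1, which encodes a macrophage surface receptor, by 0.58 ± 0.16. None of these genes is specific to red pulp macrophages, so the list name, here and below, does not single out that cell type. Without zQ175 unimmunized array 3, C1qa and Adgre1 had adjusted p-values of 0.0535 and 0.0603. With the immediate early list mean as a covariate Mertk stood at -0.042 ± 0.26, C1qa at 0.0074 ± 0.21, Adgre1 at 0.0079 ± 0.21, Timd4 at -0.040 ± 0.25 and Marco at -0.24 ± 0.16. Timd4, a phosphatidylserine receptor gene of tissue macrophages, fell by 1.03 ± 0.22. Of 17 NK and cytotoxic cell genes 7 fell and 1 rose (8 and 2 adjusted over the list alone), with a mean of -0.28 and an adjusted p = 0.676 with an estimated correlation. The granzyme A gene Gzma fell by 0.99 ± 0.23, S1pr5 by 0.80 ± 0.16 and Klrg1 by 0.59 ± 0.14. The NK cell receptor gene Klra9 fell by 1.01 ± 0.26. Under the immediate early covariate Klra9 stood at -0.795 ± 0.425, Gzma at -0.662 ± 0.369, Klrg1 at -0.404 ± 0.214 and S1pr5 at -0.382 ± 0.238. None of them passed in that fit. The other largest falls were those of Nanp (-1.13 ± 0.23), Ifit1bl1 (-1.11 ± 0.21), Adam23 (-1.02 ± 0.14), Zfp759 (-0.97 ± 0.21) and the secreted phospholipase gene Pla2g2d (-0.97 ± 0.20).

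Further shifts were seen for the remaining lists called in zQ175 spleens. Of 14 complement genes 2 fell and 1 rose (9 and 2 adjusted over the list alone), with a fall of Cfb by 0.55 ± 0.12 (adjusted p = 0.603 with an estimated correlation for the list). Of 18 mature B cell genes 3 fell and 0 rose (6 and 0 adjusted over the list alone), including the B cell receptor subunit gene Cd79b (-0.19 ± 0.050; adjusted p = 0.703 with an estimated correlation for the list). Of 15 stroma and endothelium genes 2 fell and 0 rose (3 and 0 adjusted over the list alone), including the VEGF receptor gene Kdr (-0.28 ± 0.076; adjusted p = 0.453 with an estimated correlation for the list). Of 24 S phase genes 2 rose and 0 fell, both over all genes and adjusted over the list alone, namely Cdt1 (0.45 ± 0.073) and Pcna (0.35 ± 0.076), with an adjusted p = 0.703 with an estimated correlation for the list. One of 27 G2 and M phase genes, Cks2, rose (0.73 ± 0.18; 1 adjusted over the list alone; adjusted p = 0.794 with an estimated correlation for the list). Among 19 erythroid genes 1 rose, the transferrin receptor gene Tfrc (0.71 ± 0.21; 1 adjusted over the list alone; adjusted p = 0.794 with an estimated correlation for the list). Tfrc did not pass without zQ175 immunized arrays 1 or 4 or unimmunized arrays 2 or 4, with an adjusted p of up to 0.097.

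In an exact two-sided permutation test of the list means, 6 lists passed in zQ175 spleens: immediate early, heat shock, TNF and NF-kB, neutrophil and primary granule genes, which were higher, and NK cell genes, which were lower. Each had the smallest p that the 252 splits allow (exact p = 0.00794, adjusted p = 0.0450). The red pulp macrophage list did not pass (exact p = 0.0397, adjusted p = 0.108). The count of 1881 genes was 1235 without zQ175 unimmunized array 5, 763 with the erythroid and neutrophil list means as covariates, 3763 with array weights and 2930 without R6/1 immunized array 4 and zQ175 unimmunized array 1, the latter being the unimmunized zQ175 array with a high immediate early mean. Of the 49 named genes 27 passed under every alternative fixed beforehand other than leaving out an array, and with the erythroid and neutrophil covariates the named neutrophil, primary granule and basophil genes and Gzma, Klrg1, Cfb, Cd79b, Kdr, Pcna, Cks2, Tfrc and Ppbp did not pass. The covariates are the means of lists that hold the neutrophil genes and Tfrc. For these genes the loss was built into that fit and says little about their change, and the count of 27 includes that fit.

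**Figure D2:**
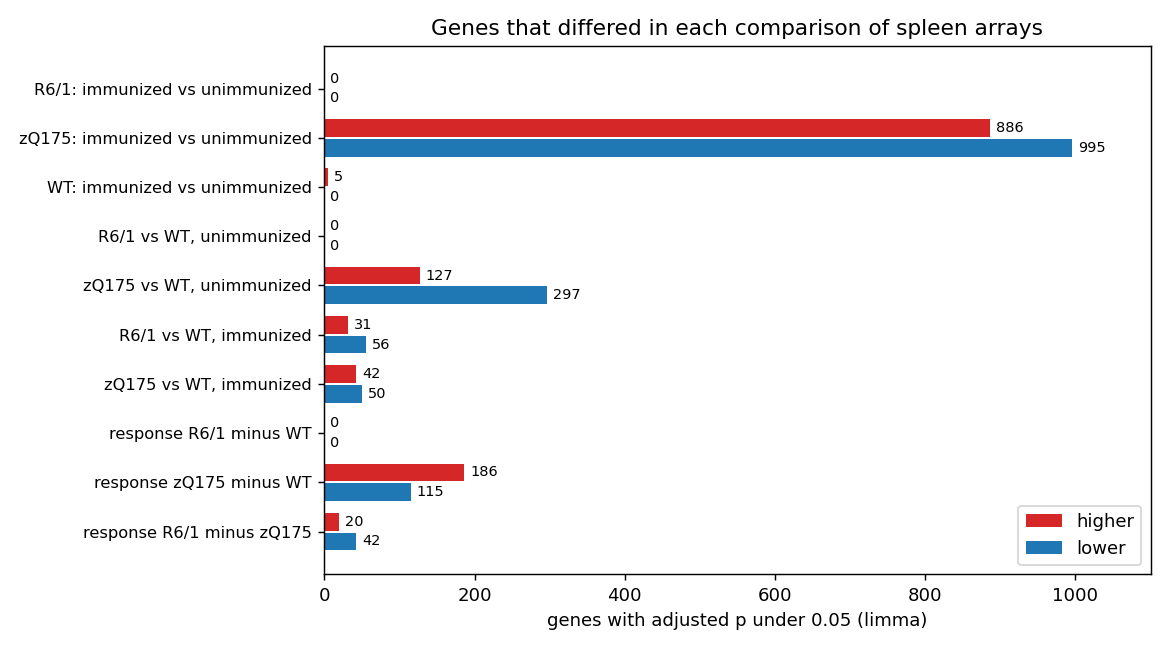
Bars give the number of genes with an adjusted p under 0.05 by limma (horizontal axis) that were higher (red) or lower (blue) in the first-named group, for each of 10 comparisons (vertical axis). The zQ175 immunization response had 886 genes higher and 995 lower, and the R6/1 response had 0.

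In WT spleens, the same comparison asked what immunization did in mice without a huntingtin mutation. In immunized WT mice 5 genes passed, all of them higher: 4 variable segments of immunoglobulin light chains and the myeloperoxidase gene Mpo. The light chain variable segments Igkv15-103 (0.64 ± 0.11, adjusted p = 0.0177), Igkv1-133 (0.50 ± 0.081, adjusted p = 0.00795), Igkv9-120 (0.50 ± 0.076, adjusted p = 0.00585) and Iglv1 (0.70 ± 0.13, adjusted p = 0.0377) rose, as did Mpo (1.69 ± 0.31, adjusted p = 0.033). All 18 immunoglobulin variable segments tested had a log2 change above 0 in WT mice, with a mean of 0.48, and 4 of them rose. In R6/1 mice 18 of 18 were above 0 (mean 0.32, 0 passed) and in zQ175 mice 17 of 18 (mean 0.31, 3 rose). These segments were not tested as a set.

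Neutrophil genes had a mean change of 0.96 in WT spleens, and 19 of 21 were above 0. None passed over all genes, and 14 did adjusted over the list alone (adjusted p = 0.337 with an estimated correlation). Camp stood at 1.94 ± 0.47, Ltf at 1.98 ± 0.50, Ngp at 1.59 ± 0.38 and Lcn2 at 1.42 ± 0.31, with adjusted p-values from 0.118 to 0.251. Of the 10 primary granule genes Mpo rose (6 adjusted over the list alone; adjusted p = 0.337 with an estimated correlation), while Elane (1.80 ± 0.38) and Ctsg (1.65 ± 0.38) did not pass. All 27 G2 and M phase genes were above 0, with a mean of 0.52 (0 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation). Among them the proliferation marker Mki67 stood at 1.15 ± 0.37 and the cyclin gene Ccna2 at 0.86 ± 0.33. All 19 erythroid genes were above 0, with a mean of 1.02 and an adjusted p = 0.350 with an estimated correlation. Adjusted over the list alone, 1 of them passed. Among them Kel stood at 1.68 ± 0.65 and Mt2, a metallothionein gene that is not specific to red cells, at 1.11 ± 0.32.

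Plasma cell genes had a mean of 0.10 in WT spleens, with 19 of 21 above 0 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.337 with an estimated correlation). The joining chain gene Jchain stood at 0.35 ± 0.091 and Derl3 at 0.51 ± 0.14. None of the 17 NK cell genes was above 0, with a mean of -0.29 (0 adjusted over the list alone; adjusted p = 0.337 with an estimated correlation), Gzma at -0.67 ± 0.25 and Klrg1 at -0.42 ± 0.14. The 13 germinal centre B cell genes had a mean of -0.14 (0 adjusted over the list alone; adjusted p = 0.558 with an estimated correlation), with Rgs13 at -0.74 ± 0.27. On the germinal centre list WT unimmunized array 4 stood apart, at 8.823 against 8.428 to 8.538 in the rest of its group. The 3 lowest p-values among falls were those of Ell2 (-0.84 ± 0.18), Ubxn6 (-0.28 ± 0.060) and Ccl6 (-0.51 ± 0.12), none of which passed. Apart from the light chain segments, for which this was not counted, the named genes lay beyond the unimmunized mean in 4 of 4 immunized arrays. The count of 5 was 3, 10, 0 and 1 without WT immunized arrays 1 to 4, 2 without each of WT unimmunized arrays 2 to 4 and 11 without WT unimmunized array 5, and Mpo had an adjusted p of up to 0.37. With only the WT arrays in the fit, or with the erythroid and neutrophil list means as covariates, the count was 0.

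In R6/1 spleens, no gene passed between immunized and unimmunized mice, where limma gave 905 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.216. The smallest p-values among named genes were those of Zfp691 (0.58 ± 0.12), Ocstamp (0.39 ± 0.083) and the Notch target gene Hey1 (0.65 ± 0.14) on the higher side and Zfp709 (-0.36 ± 0.083), Zfp282 (-0.37 ± 0.088) and Mfsd1 (-0.22 ± 0.053) on the lower side, with adjusted p-values of 0.339 to 0.367 and each in 5 of 5 arrays. Neutrophil genes had a mean of 0.35, with Ltf at 1.02 ± 0.47 and Ngp at 0.96 ± 0.35. The TNF and NF-kB list had a mean of 0.11, with the cytokine gene Tnf at 0.61 ± 0.19 and Ccl2 at 0.53 ± 0.17. Red pulp macrophage genes had a mean of -0.24, with the haemoglobin receptor gene Cd163 at -0.60 ± 0.20. On that list R6/1 immunized array 5 stood apart, at 9.695 against 8.82 to 8.972 in the rest of its group. NK cell genes had a mean of -0.19, with Gzma at -0.62 ± 0.23 and the NK cell receptor gene Ncr1 at -0.62 ± 0.23. Each of these 4 lists had an adjusted p = 0.820 with an estimated correlation and 0 members that passed, over all genes or adjusted over the list alone. Without R6/1 immunized array 5 the count was 12 genes, 5 higher and 7 lower.

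**Figure D3:**
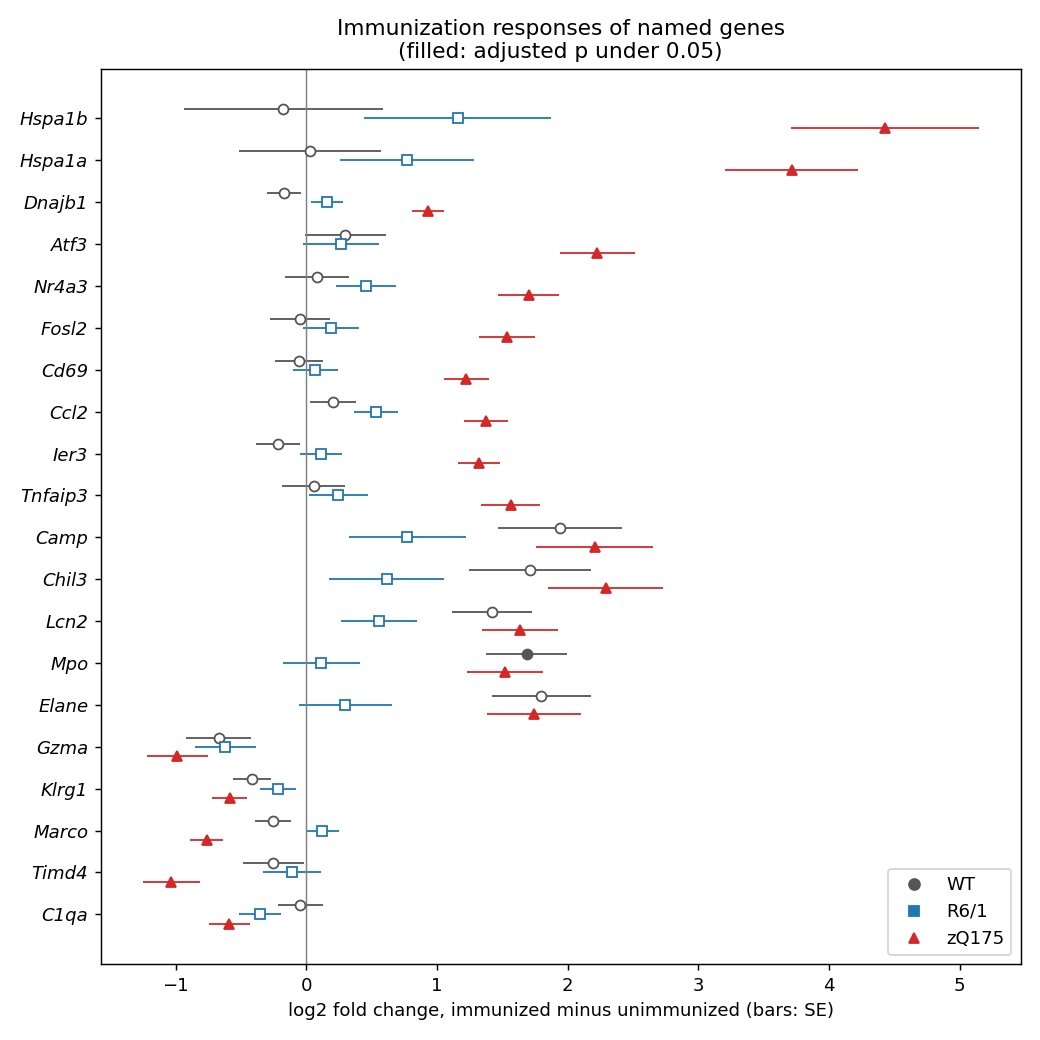
Points give the log2 fold change from unimmunized to immunized spleens (horizontal axis) of 20 genes (vertical axis) in WT, R6/1 and zQ175 mice, with bars for the SE. Filled symbols have an adjusted p under 0.05 by limma. Hspa1b stood at 4.43 in zQ175 mice, and Mpo passed in zQ175 (1.52) and WT mice (1.69).

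The next comparison asked whether the genotypes differed in their response to immunization. The zQ175 and WT responses differed for 301 genes, 186 with a higher and 115 with a lower change in zQ175. With array weights there were 775 higher and 976 lower, which turns the larger share. The largest differences were those of Hspa1b (4.60 ± 1.05, adjusted p = 0.0189), Hspa1a (3.69 ± 0.75), Rgs16 (2.51 ± 0.39), Klf4 (2.14 ± 0.57) and Acod1, which encodes the itaconate-producing enzyme of activated macrophages (2.07 ± 0.38). Of the immediate early genes 15 of 25 were higher in this difference (23 adjusted over the list alone; adjusted p = 0.111 with an estimated correlation), including Fosl2 (1.58 ± 0.32). So were 10 of 27 TNF and NF-kB genes (13 adjusted over the list alone; adjusted p = 0.0564 with an estimated correlation), including Ier3 (1.54 ± 0.23), and 4 of 12 heat shock genes (9 adjusted over the list alone; adjusted p = 0.0564 with an estimated correlation). Against WT the immediate early list stood at -0.711 ± 0.173 among unimmunized and 0.28 ± 0.183 among immunized zQ175 mice. The larger estimate was thus that among unimmunized mice. The heat shock list stood at -0.396 ± 0.153 and 0.676 ± 0.162 and the TNF and NF-kB list at -0.234 ± 0.0887 and 0.372 ± 0.0941. For these lists the larger estimate was that among immunized mice. Whether the sizes among unimmunized and immunized mice differ was not tested for any of these lists. The inhibitory T cell receptor gene Ctla4 differed by 1.25 ± 0.29. Lower in zQ175 were Zfp759 (-1.21 ± 0.30), Adam23 (-0.99 ± 0.21) and the potassium channel gene Kcnj16 (-0.98 ± 0.19). The neutrophil list differed by 0.35 ± 0.44, which is within its error.

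The count of 301 was 826 without zQ175 unimmunized array 1. It was 165, 169, 154 and 124 without zQ175 unimmunized arrays 2 to 5, 199 without zQ175 immunized array 5, 150, 159 and 146 without WT immunized arrays 2 to 4, 156 and 175 without WT unimmunized arrays 1 and 2, and 0 with the immediate early covariate. In the 19 fits that left out 1 array, Klf4, Zfp759 and Ctla4 did not pass in 17, 10 and 3, with values of up to 0.0993, 0.0921 and 0.0536.

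Between R6/1 and zQ175 the responses differed for 62 genes, 20 higher and 42 lower in R6/1. Lower in R6/1 were Atf3 (-1.96 ± 0.41), the pattern recognition receptor gene Clec4e (-1.64 ± 0.37), Acod1 (-1.63 ± 0.37), the immediate early genes Fosb (-1.61 ± 0.38) and Nr4a2 (-1.48 ± 0.32) and Hdc (-1.43 ± 0.29), and higher were Ifit1bl1 (1.30 ± 0.30) and Marco (0.89 ± 0.18). Of the immediate early genes 5 of 25 were lower (21 adjusted over the list alone) and of the heat shock genes 1 of 12 (7 adjusted over the list alone), each list with an adjusted p = 0.222 with an estimated correlation. The count of 62 was 0 without any one of R6/1 immunized arrays 3 to 5, zQ175 immunized arrays 1, 2, 3 and 5, zQ175 unimmunized arrays 2 to 5 and R6/1 unimmunized arrays 1 and 2. It was 25 without zQ175 immunized array 4, 27, 18 and 164 without R6/1 unimmunized arrays 3 to 5, 582 without zQ175 unimmunized array 1 and 0 with only the arrays of these groups. None of the 8 genes named passed in all 20 fits.

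Between R6/1 and WT no gene differed in its response, where limma gave 807 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.768. Mpo stood at -1.57 ± 0.43, Mki67 at -1.25 ± 0.51 and Rgs13 at 1.05 ± 0.37. The G2 and M phase list had a mean of -0.62 and the erythroid list a mean of -1.13, with 0 members adjusted over the list alone and an adjusted p = 0.706 with an estimated correlation for each.

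Among unimmunized mice, the comparison with WT asked what each mutation does in the resting spleen. In zQ175 spleens 424 genes differed from WT, 127 higher and 297 lower. Among the lists described here, the immediate early list had the most genes that fell, and these were 18 of the 297. Of the 25 immediate early genes 18 fell and 0 rose (23 and 0 adjusted over the list alone), with a mean of -0.71 and an adjusted p = 0.338 with an estimated correlation. Atf3 differed by -1.65 ± 0.29 (adjusted p = 0.00308), Nr4a1 by -1.22 ± 0.21, Cd69 by -1.03 ± 0.17 and Csrnp1 by -0.97 ± 0.18. Other large falls were those of Klf4 (-1.52 ± 0.39), the kinase gene Plk2 (-1.40 ± 0.34), Zbtb10 (-1.30 ± 0.28), Rgs16 (-1.28 ± 0.27), Rasd1 (-1.14 ± 0.21) and Bambi, a decoy receptor gene of TGF-beta signalling (-1.13 ± 0.16, adjusted p = 0.000267). Heat shock genes fell in 2 of 12 cases (6 adjusted over the list alone; mean -0.40; adjusted p = 0.338 with an estimated correlation), Hsph1 by 0.94 ± 0.16 and Chordc1 by 0.59 ± 0.11. TNF and NF-kB genes fell in 5 of 27 cases and rose in 0 (6 and 1 adjusted over the list alone; mean -0.23; adjusted p = 0.787 with an estimated correlation), including Tnfaip3 (-1.12 ± 0.23), the chemokine gene Ccl4 (-0.99 ± 0.20) and Ier3 (-0.77 ± 0.16).

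Higher in unimmunized zQ175 than in WT spleens were Nanp (0.83 ± 0.23), Tbc1d7 (0.62 ± 0.091, adjusted p = 0.000604), Adam23 (0.59 ± 0.14), the cell cycle kinase gene Wee1 (0.58 ± 0.16), Kcnj16 (0.57 ± 0.13), Gpr155 (0.57 ± 0.099), the interferon-inducible GTPase gene Irgm2 (0.56 ± 0.15) and Zfp366 (0.56 ± 0.14). The complement receptor gene Cr2 of B cells rose by 0.42 ± 0.085. In the Toll-like receptor list 2 of 27 genes rose, Tlr11 (0.54 ± 0.14) and Tlr6 (0.43 ± 0.11), with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.787 with an estimated correlation). The G2 and M phase list had a mean of 0.52 (11 adjusted over the list alone), with Mki67 at 0.99 ± 0.35 and Cdk1 at 0.89 ± 0.29. The erythroid list had a mean of 0.82 (2 adjusted over the list alone), with the carbonic anhydrase gene Car1 at 1.47 ± 0.45, and the red pulp macrophage list one of 0.31 (0 adjusted over the list alone), with its transcription factor gene Spic at 0.58 ± 0.22. None of the members of these 3 lists passed over all genes, and each list had an adjusted p = 0.787 with an estimated correlation. Named genes that passed were on their side of the WT mean in 5 of 5 zQ175 arrays or in 4 of 5, array 1 being the exception for the immediate early list mean.

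The count of 424 was 1110 without zQ175 unimmunized array 1, 156, 104 and 158 without zQ175 unimmunized arrays 3, 4 and 5, and 205 and 193 without WT unimmunized arrays 1 and 4. It was 20 with only the arrays of both groups in the fit, 114 with the erythroid and neutrophil covariates and 4 with the immediate early covariate, and of the 26 named genes that passed 15 did so in every fit that left out 1 array. Of 10 such fits Nanp did not pass in 9, Wee1 and Zfp366 in 8, Irgm2 in 7, Klf4, Tlr6 and Tlr11 in 6, Plk2, Adam23 and Kcnj16 in 5 and Zbtb10 in 1, and only Tbc1d7 passed under every other alternative fixed beforehand.

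In unimmunized R6/1 spleens no gene differed from WT, where limma gave 822 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.216. The lowest p-values were those of Endou (0.74 ± 0.15), the interleukin 12 subunit gene Il12a (0.52 ± 0.11) and Lrmp (0.36 ± 0.074) on the higher side and Pde3b (-0.63 ± 0.15), Chst10 (-0.58 ± 0.14) and the co-chaperone gene Stip1 (-0.37 ± 0.091) on the lower side, each in 5 of 5 arrays. None of the 18 red pulp macrophage genes was above 0 (mean -0.35), with the haem oxygenase gene Hmox1 at -0.62 ± 0.26 and Marco at -0.30 ± 0.13. T cell genes had a mean of -0.19, with Cd4 at -0.32 ± 0.13 and Cd6 at -0.23 ± 0.073. Type I interferon response genes had a mean of 0.18, with Mx2 at 0.60 ± 0.19 and Oas2 at 0.53 ± 0.21, and plasma cell genes one of 0.081, with the syndecan gene Sdc1 at 0.31 ± 0.10. Adjusted over the list alone, 2 plasma cell genes were higher and no gene of the other 3 lists passed, and each of the 4 lists had an adjusted p = 0.587 with an estimated correlation. With array weights 6 genes passed, all higher.

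After immunization, 87 genes differed between R6/1 and WT spleens, 31 higher and 56 lower. Rgs13, a germinal centre B cell gene, rose most (1.35 ± 0.27, adjusted p = 0.0324), followed by Rgs16 (1.23 ± 0.28), Pcp4 (1.07 ± 0.25), Gadd45g (0.95 ± 0.22) and Hey1 (0.76 ± 0.15). Lower in R6/1 were the transporter gene Abcc3 (-1.05 ± 0.24), the interleukin 9 receptor gene Il9r (-1.04 ± 0.20, adjusted p = 0.0285), the mannose receptor gene Mrc1 (-1.01 ± 0.23), the eosinophil chemokine receptor gene Ccr3 (-0.99 ± 0.24) and Cd163 (-0.93 ± 0.21). Each was on its side of the WT mean in 5 of 5 arrays. Red pulp macrophage genes fell in 3 of 18 cases and rose in 0 (15 and 0 adjusted over the list alone; mean -0.63; adjusted p = 0.676 with an estimated correlation), including Vcam1 (-0.87 ± 0.18). One of 13 germinal centre genes rose (4 adjusted over the list alone; mean 0.31; adjusted p = 0.536 with an estimated correlation), and the nuclear GTPase gene Nuggc stood at 0.38 ± 0.10 (adjusted p = 0.0627). Csf1r, the macrophage growth factor receptor gene, stood at -0.75 ± 0.20 (adjusted p = 0.0654). The count of 87 was 4, 5, 6, 20 and 921 without R6/1 immunized arrays 1 to 5 and 19, 3, 5 and 3 without WT immunized arrays 1 to 4, and 0 with only these arrays in the fit. None of the 11 named genes that passed did so in every fit that left out 1 array. R6/1 immunized array 4, which stood apart from all others, was among these arrays, and the 20 genes without it were 15 higher and 5 lower, which turns the larger share from lower to higher. Without it and zQ175 unimmunized array 1 they were 25, with 18 higher and 7 lower.

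Between immunized zQ175 and WT spleens 92 genes differed, 42 higher and 50 lower. Heat shock and inflammatory genes were higher in zQ175: Hspa1b (3.76 ± 0.76), Hspa1a (3.17 ± 0.54, adjusted p = 0.0069), Dnajb1 (0.69 ± 0.13), Acod1 (1.57 ± 0.28), Clec4e (1.28 ± 0.28), the myeloid receptor gene Trem1 (1.25 ± 0.30), Tnf (0.99 ± 0.20) and the NF-kB inhibitor gene Nfkbia (0.81 ± 0.16). Of 27 TNF and NF-kB genes 5 rose and 0 fell (11 and 0 adjusted over the list alone; mean 0.37; adjusted p = 0.129 with an estimated correlation), and of 12 heat shock genes 3 rose and 0 fell (4 and 1 adjusted over the list alone; mean 0.68; adjusted p = 0.237 with an estimated correlation). No neutrophil gene passed over all genes and 10 did adjusted over the list alone (mean 0.74; adjusted p = 0.237 with an estimated correlation), with the G-CSF receptor gene Csf3r at 1.00 ± 0.27. The immediate early list had a mean of 0.28 with 0 genes that passed, over all genes or adjusted over the list alone (adjusted p = 0.677 with an estimated correlation). Lower in zQ175 were Slc37a2 (-0.60 ± 0.089, adjusted p = 0.00184), Zfp994 (-0.56 ± 0.13), Htt (-0.51 ± 0.12), Ubfd1 (-0.45 ± 0.095) and Banp (-0.45 ± 0.089). Each named gene was on its side of the WT mean in 5 of 5 zQ175 arrays. The count of 92 was 9, 32, 11 and 39 without zQ175 immunized arrays 1 to 4 and 19, 11, 15 and 11 without WT immunized arrays 1 to 4. Of the genes named, only Hspa1a and Slc37a2 passed in every fit that left out 1 array. More genes were higher than lower, unlike in the count of 92, under quantile normalization (47 and 31), with each array centred (16 and 4), with no filter (19 and 6), with the erythroid and neutrophil covariates (18 and 1), with only these arrays in the fit (160 and 123) and without any one of zQ175 immunized arrays 1 to 4 and WT immunized arrays 1, 2 and 4.

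Htt itself had a mean log2 expression of 9.64 ± 0.18 (SD, n = 5) in unimmunized and 9.85 ± 0.059 (SD, n = 4) in immunized WT spleens. It was 9.35 ± 0.13 and 9.33 ± 0.18 in zQ175 spleens (SD, n = 5 each) and 9.56 ± 0.22 and 9.51 ± 0.27 in R6/1 spleens (SD, n = 5 each). Against unimmunized WT the zQ175 difference was -0.29 ± 0.11 (adjusted p = 0.159) and the R6/1 difference -0.079 ± 0.11 (adjusted p = 0.991). The zQ175 difference among immunized mice had an adjusted p = 0.0434, which did not hold without any one of 8 of the 9 arrays (up to 0.147), and the R6/1 difference was -0.34 ± 0.12 (adjusted p = 0.128). Which part of the gene its 1 probe set covers was not analysed here.

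A further question was whether the difference of zQ175 from WT spleens was kept after immunization. Of the 424 genes that differed before, 9 did so after immunization, 5 of them in the same direction, and 144 were among the genes whose response differed between zQ175 and WT. The median size of the difference was 0.38 before and 0.12 after. These genes were picked for their difference before immunization, which is also a term of the difference between responses. The count of 144 and the smaller median after immunization thus follow in part from the picking. Of the 297 genes lower in unimmunized zQ175 than in WT spleens 196, among them Atf3, Klf4 and Cd69, rose on immunization, and of the 127 higher genes 88, among them Adam23 and Nanp, fell. Unrelated lists would share 19.6 and 9.42, but both differences use the same unimmunized zQ175 arrays, and their correlation across genes (r = -0.491) was near the median of simulations of unchanged groups (-0.497), while their covariance of -0.023 was further from 0 than the simulated mean of -0.00726. With these arrays split between the differences, the correlation had a median of -0.304 and a range of -0.423 to -0.0788 over 20 settings. The slope of the later on the earlier difference was -0.204 over the 424 genes. When genes were picked on part of the unimmunized arrays and measured on the rest, over 100 splits, that slope had a median of 0.0378. Its range was -0.476 to 0.223, so the sign was not kept. Genes are not independent replicates in these correlations.

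The R6/1 and zQ175 differences from unimmunized WT spleens had a correlation of 0.264 across genes. They share the WT arrays, and simulations of unchanged groups gave a median of 0.497 and a 5th to 95th percentile range of 0.0734 to 0.81. With the WT arrays split between them the median was -0.00745 and the range -0.186 to 0.156 over 20 settings. The immunization responses share no arrays. Their correlations across genes were 0.358 for R6/1 with zQ175, 0.29 for zQ175 with WT and 0.135 for R6/1 with WT. Simulations of unchanged groups gave a median of -0.0868 and a 5th to 95th percentile range of -0.549 to 0.388. These correlations lay within that range, but it is so wide that they neither show nor exclude a relation between the responses. Of the 5 genes that rose in WT spleens 3, Mpo among them, also rose in zQ175 spleens, where unrelated lists would share 0.33.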

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

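The tests of handling, of added neutrophils, of scaling, of background and of a mislabelled array were chosen after the results they bear on were seen.

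The first pattern is that immediate early and heat shock genes had higher list means in immunized than in unimmunized zQ175 spleens. Against WT the immediate early mean was -0.711 ± 0.173 among unimmunized and 0.28 ± 0.183 among immunized zQ175 mice, and the heat shock mean was -0.396 ± 0.153 and 0.676 ± 0.162. The larger heat shock estimate was that among immunized mice, but whether these sizes differ was not tested. Against scaling, the immediate early change was 0.995 ± 0.169 under quantile normalization, against 1.03. Against neutrophils that bring their own transcripts as the whole cause, the changes with the erythroid and neutrophil list means as covariates were 1.19 ± 0.23 (immediate early), 1.29 ± 0.209 (heat shock) and 0.54 ± 0.128 (TNF and NF-kB), in a test run after 2 others had been seen: an immediate early change of 0.0347 ± 0.183 in WT mice, where 0.753 was needed but the bound of 0.376 lay below its upper limit of 0.401 (2 SE), and a comparison of unimmunized genotypes (0.395 ± 0.302, where -0.91 was needed), which excludes nothing within zQ175 mice. Handling of the unimmunized or the immunized spleens cannot be told apart from a response, since no label gives a batch that holds both groups, and the age of the mice, the genotype and the immunization stay open as untested biology.

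The second pattern is that neutrophil and primary granule genes were higher in immunized than in unimmunized zQ175 spleens. If the immediate early shift of the same arrays were its cause, the neutrophil change would be near 0 with the immediate early list mean as a covariate, and it was 1.84 ± 0.471 against 1.31 ± 0.302 without it. Within groups that covariate varied most among the unimmunized zQ175 arrays (SD 0.581, against 0.0308 to 0.199 in the other groups), where array 1 stood apart. The fit thus leans on few arrays and cannot exclude the immediate early shift as a cause. The erythroid mean also went up in that fit, from 0.46 ± 0.471 to 1.47 ± 0.716, so the growth of the change is not specific to granulocytes. No single gene passed in that fit, in which Chil3 stood at 3.39 ± 0.66 (adjusted p = 0.0708) against 2.29 ± 0.44 and Lcn2 at 2.35 ± 0.44 (adjusted p = 0.0708) against 1.63 ± 0.29, so that change and SE grew together; the adjusted p also depends on how many other genes have small p-values, and what ended the calls was not tested. A larger share of granulocytes in the spleen, from the immunization or the age of the mice, stays open as a hypothesis, since no cell counts were used here.

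The third pattern is that R6/1 immunized array 4 stood apart from all other arrays. Its olfactory and vomeronasal receptor probe sets (1407), which spleen cells are not known to express, had a median of 4.23, against 3.707 to 3.878 on the other arrays (SD 0.038), and raised background on that array may account for its distance. Against a mislabelled array of another group, its highest correlation with any array was 0.9726, where the lowest best match of the other arrays was 0.9884. A biological cause was not tested.

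Single arrays far from the rest of their group numbered 21 in 228 tests, where chance gives 11.4. The mean correlation with the 28 other arrays was 0.9663 for R6/1 immunized array 4 (others of its group 0.9859 to 0.9879) and 0.982 for zQ175 immunized array 1 (0.9859 to 0.9873). The SD over probe sets was 2.164 for R6/1 immunized array 4 (2.289 to 2.309) and 2.275 for zQ175 unimmunized array 4 (2.297 to 2.302), and the olfactory median of the former was 4.231 (3.732 to 3.777). Among list means, zQ175 unimmunized array 1 had 10.5 for the unfolded protein response (10.13 to 10.21), 8.953 for follicular helper T cells (8.712 to 8.778), 6.999 for stroma (7.231 to 7.275) and 8.442 for complement (8.9 to 9.028). In the same group array 4 had 7.244 for exocrine pancreas (6.248 to 6.35), an organ next to the spleen. WT unimmunized array 4 had 8.823 for germinal centre genes (8.428 to 8.538) and 9.129 for the interferon gamma response (8.856 to 8.892), array 2 had 7.262 for stroma (7.09 to 7.136) and array 5 had 11.23 for immediate early genes (11.39 to 11.44). WT immunized array 1 had 10.5 for the unfolded protein response (10.41 to 10.42) and array 3 had 8.954 for primary granule genes (8.092 to 8.234). R6/1 unimmunized array 5 had 11.1 for immediate early genes (11.46 to 11.57) and 10.13 for proteasome and autophagy genes (10.24 to 10.28). R6/1 immunized array 4 had 8.144 for T helper factors (8.511 to 8.627) and array 5 had 9.695 for red pulp macrophages (8.82 to 8.972). zQ175 immunized array 2 had 8.789 for genes known to differ between inbred strains (8.952 to 9.005).

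Differences between immunization responses were tested directly. Between zQ175 and WT 301 genes and 8 lists differed, among them Hspa1b (4.60), Hspa1a (3.69), Rgs16 (2.51), Klf4 (2.14), Acod1 (2.07), Fosl2 (1.58), Ier3 (1.54), Ctla4 (1.25), Kcnj16 (-0.98), Adam23 (-0.99) and Zfp759 (-1.21). Between R6/1 and zQ175 62 genes and 15 lists differed, among them Atf3 (-1.96), Clec4e (-1.64), Acod1 (-1.63), Fosb (-1.61), Nr4a2 (-1.48), Hdc (-1.43), Marco (0.89) and Ifit1bl1 (1.30). Between R6/1 and WT 12 lists differed. None of these list differences passed with an estimated correlation.

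Of the probe sets without a gene of their own, 8647 were expressed and tested apart from the genes. In zQ175 spleens 914 changed on immunization, 760 of them higher and 154 lower, and in WT spleens 24 (20 and 4). Between unimmunized zQ175 and WT spleens 85 differed (24 higher and 61 lower), and between immunized ones 3 were higher.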

How the results depend on the processing

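The fits without R6/1 immunized array 4 and zQ175 unimmunized array 1 together, with the immediate early list mean as a covariate, and the exact permutation of list means were chosen after the data were seen. Of 1790 values for 180 named gene results under the alternatives fixed beforehand, 1578 kept their direction and their side of the threshold, 188 no longer passed, 24 newly passed and 0 reversed. Of 1955 values with 1 array left out, the numbers were 1557, 384, 14 and 0. Of 360 under the added alternatives they were 246, 101, 5 and 8. All 8 reversals came with the immediate early covariate: Klf4 (-0.26), Ddit3 (-0.21), Dnajb9 (-0.062), C1qa (0.0074) and Adgre1 (0.0079) in the zQ175 response, Klf4 (0.14) and Plk2 (0.0071) between unimmunized zQ175 and WT mice and Klf4 (-0.18) in the difference between the zQ175 and WT responses. Of 306 list values under the former 214 stayed and 92 no longer passed, of 562 with 1 array left out 524 and 38, and of 95 under added ones 53 and 42. Expression of genes near background was limited by the array signal, since the median of the table, 6.267, was the filter. A change of the added constant before taking logs was not run, because the values were already log2. Except where a change of fitted arrays or tested genes is the setting itself, the cause was not tested.

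Counts of genes are given in the order zQ175 response, WT response, zQ175 against WT unimmunized, R6/1 against WT immunized, zQ175 against WT immunized, zQ175 minus WT response and R6/1 minus zQ175 response, where they were 1881, 5, 424, 87, 92, 301 and 62. With array weights they were 3763, 39, 2156, 1030, 1347, 1751 and 727, and R6/1 against WT unimmunized gave 6 against 0. Without R6/1 immunized array 4 and zQ175 unimmunized array 1 they were 2930, 8, 1483, 25, 309, 1088 and 630, and the R6/1 response had 5 lists against 10. For the settings that follow, only counts that moved by over 1.5 times are given. With erythroid and neutrophil list means as covariates the first 5 were 763, 0, 114, 2 and 19. With the immediate early list mean as a covariate the zQ175 response had 0, zQ175 against WT unimmunized 4, zQ175 against WT immunized 22, and both differences between responses 0. With no filter zQ175 against WT unimmunized had 277, R6/1 against WT immunized 9, zQ175 against WT immunized 25, zQ175 minus WT 173 and R6/1 minus zQ175 0, and the stricter filter gave 141 for R6/1 against WT immunized. With only the arrays of the groups compared the WT response had 0, zQ175 against WT unimmunized 20, R6/1 against WT immunized 0, zQ175 against WT immunized 283 and R6/1 minus zQ175 0. With each array centred on its median R6/1 against WT immunized had 18 (7 higher and 11 lower), zQ175 against WT immunized 20 (16 and 4) and R6/1 minus zQ175 0. With the replicate block the WT response had 1, R6/1 against WT immunized 766, zQ175 against WT immunized 294, zQ175 minus WT 537 and R6/1 minus zQ175 171. Whether the numbers pair the samples is not known. Deviations from group means were correlated between unimmunized and immunized arrays of the same number. The mean r was 0.153 in R6/1 (other numbers -0.0375), 0.0414 in WT (-0.0089) and -0.041 in zQ175 mice (0.0114).

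Under quantile normalization the split between higher and lower genes was 855 and 1712 for the zQ175 response, 36 and 38 for R6/1 against WT immunized, 47 and 31 for zQ175 against WT immunized and 35 and 41 for R6/1 minus zQ175. With the WT arrays split, the correlation of the R6/1 and zQ175 differences had a median of -0.00745, against 0.264. With genes picked on part of the unimmunized arrays the slope of the zQ175 difference after on before immunization had a median of 0.0378, against -0.204.

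With 1 array left out, genes ranged from 0 to 12 for the R6/1 response, 1235 to 2478 for zQ175, 0 to 11 for WT, 0 to 0 for R6/1 against WT unimmunized, 104 to 1110 for zQ175 against WT unimmunized, 3 to 921 for R6/1 against WT immunized, 9 to 94 for zQ175 against WT immunized, 0 to 0 for R6/1 minus WT, 124 to 826 for zQ175 minus WT and 0 to 582 for R6/1 minus zQ175. Lists in the same order ranged from 6 to 11, 11 to 16, 10 to 15, 10 to 14, 8 to 15, 9 to 17, 11 to 15, 10 to 17, 5 to 12 and 11 to 17. The lowest values came without R6/1 unimmunized array 5 for the R6/1 response (6), without WT immunized array 3 for R6/1 against WT immunized (9) and without WT unimmunized array 5 for zQ175 minus WT (5).

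With the correlation estimated per list, camera called 0 lists in each of the 10 comparisons. The function fry called 10 in the zQ175 response, 2 for zQ175 against WT unimmunized, 1 for zQ175 against WT immunized, 3 each for zQ175 minus WT and R6/1 minus zQ175 and 0 in the other 5. The exact permutation of list means gave 6 in the zQ175 response and 0 in the other 6 comparisons of groups.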

Other observations

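The tests of other splits and of variation in cell make-up between animals were chosen after the results they bear on were seen.

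Small nuclear and nucleolar RNA genes, of which 73 were tested as a class outside the lists, had lower means in immunized than in unimmunized WT spleens (9.41 ± 0.34 against 9.93 ± 0.40, SD, n = 4 and 5) and R6/1 spleens (9.62 ± 0.23 against 9.98 ± 0.19, SD, n = 5 each). In zQ175 spleens the means were 9.92 ± 0.24 and 9.89 ± 0.36 (SD, n = 5 each). By limma, 0 of these genes passed in the WT and R6/1 responses, and 3 rose and 0 fell in the zQ175 response. Between immunized zQ175 and WT spleens 2 rose and 0 fell (mean 0.51, 70 of 73 above 0). In the difference between the zQ175 and WT responses 0 passed (mean 0.55, 67 of 73 above 0). The class was looked at after its values were seen, and it was not tested as a set.

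Several immune lists were not called by camera in zQ175 spleens on immunization. These were the germinal centre (-0.079), follicular helper T cell (-0.052), T helper (0.0042), T cell (0.088) and plasma cell (0.090) lists (mean changes in brackets). So were the type I interferon (-0.14) and interferon gamma (-0.080) response lists.

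Granulocyte, erythroid and cell cycle genes had higher means in immunized than in unimmunized WT spleens. A hypothesis of red cells left after lysis was tested by the correlation of the erythroid and G2 and M list means within groups, which should be under 0.3, as reticulocytes carry no mitotic transcripts. It was r = 0.84 over 29 arrays (rho = 0.848, two-sided permutation p = 1e-05, the smallest that 1e+05 resamples can give, and 0.821 without the 2 farthest arrays). For the variation within groups, this argues against leftover red cells as the whole cause. The correlation does not test the difference between the immunized and unimmunized WT means. Variation between animals was tested by exact two-sided permutation of the WT list means. It gave unadjusted p-values of 0.007937 for the neutrophil list, 0.03968 for the G2 and M list and 0.06349 for the erythroid list. Adjusted over 34 lists none passed in WT spleens, with 0.2159 for both the G2 and M and the erythroid list. Chance variation thus remains open for each of them. The neutrophil value is the smallest that the splits allow. Its adjusted p of 0.08995 could have been lower only if more lists had reached that value. Dividing erythroid precursors, whose share may differ between animals, remain a hypothesis.

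Htt was lower in zQ175 than in WT spleens after immunization, and genes near it that come from the strain of the targeted embryonic stem cells were tested as a hypothesis. Among 100 tested neighbours of Htt (assembly GRCm38.p6) 7 passed between zQ175 and WT in either state, where the median window had 3, and 9.75% of 11327 windows had as many. A cluster of strain differences around Htt was thus not seen beyond what other windows show.

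Each count was compared with 100 splits of the same arrays into groups of the same sizes, the real one included. For the zQ175 response, 1 split gave as many as 1881 genes (highest other 1333), and for the difference between the zQ175 and WT responses 1 split gave as many as 301 (highest other 268), in each case the real one. Chance can be excluded for these at 1 of 100 splits, without allowance for the 10 comparisons. Fewer than 5 of 100 splits gave as many genes for WT mice (5 genes, 3 splits, highest other 51), zQ175 against WT among unimmunized mice (424, 4 splits, 727), zQ175 against WT among immunized mice (92, 3 splits, 210) and R6/1 against WT among immunized mice (87, 3 splits, 1130). For these 4 counts chance is excluded only if each is taken alone, other splits gave more genes than the real one, and the WT and the immunized R6/1 counts were 0 with only the arrays compared in the fit. Chance cannot be excluded for the difference between the R6/1 and zQ175 responses (62 genes, 7 splits, highest other 626). For the R6/1 response (0 genes, 100 splits, highest other 38), R6/1 against WT among unimmunized mice (0, 100 splits, 2) and the difference between the R6/1 and WT responses (0, 100 splits, 2), every split gave as many. Some splits called several times the real count, such as 1130 against 87, 626 against 62 and 51 against 5. What lies behind these counts was not tested.

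For the lists called by camera with its preset correlation, chance could not be excluded in any comparison. The counts for the responses were 10 lists in R6/1 (32 splits as large, highest other 15), 16 in zQ175 (9 splits, 17) and 13 in WT mice (11 splits, 19). Against WT they were 13 for unimmunized R6/1 (13 splits, 17), 12 for unimmunized zQ175 (33 splits, 18), 14 for immunized R6/1 (20 splits, 21) and 14 for immunized zQ175 mice (21 splits, 19). For the differences between responses they were 12 for R6/1 and WT (20 splits, 20), 8 for zQ175 and WT (76 splits, 18) and 15 for R6/1 and zQ175 (15 splits, 21).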
